A study of Homo sapiens with 2 samples.

How the data were processed

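Gene expression was measured on 2 one-colour (Cy3) Agilent whole-genome arrays, 1 for side-population (SP) cells and 1 for non-side-population (NSP) cells, both sorted from the human trophoblast cell line HTR-8/SVneo. Both arrays lay on 1 slide, so slide could not differ between the groups. Samples were grouped by the sort label, which the titles share. For the NSP sample the labels conflict: the title and the sort label name NSP cells, while the description names SP cells kept for a week in basal medium. The group names below follow the sort label. Per the labels' protocols, SP cells were kept in a medium of which 50% was conditioned by mouse embryonic fibroblasts, with heparin and 25 ng/mL FGF2, and NSP cells in serum-containing basal medium without these additions, so the sorted population and the culture medium cannot be told apart.

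Per the file headers, the deposited scanner files hold spot intensity values made by Agilent Feature Extraction 10.7.1.1, while the submitters' processing notes name version 9.5.3.1. The processed intensity in those deposited files was background-subtracted and spatially detrended by that software and was not scaled between arrays, per the file headers. Feature Extraction's own quality evaluation in the headers placed the mean signal of the negative controls outside its range on both arrays. The deposited series table was found to hold the same processed signals divided by a single factor per array, 2548 for SP and 2682 for NSP. The quotient was constant within 1% for 98.9% of the SP probes and 98.9% of the NSP probes. Its values are linear, with column medians of 0.0800 and 0.0798, and showed no centring by gene. The array grid refers to the hg19 human assembly, per the file headers.

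The log2 of each processed signal was taken relative to the array's 75th percentile over the non-control spots, which was 3455 on the SP array and 3709 on the NSP array. Control spots (1377 of 44495) and spots marked as outliers by Feature Extraction (328 on SP, 369 on NSP) were left out. No spot was saturated. Spots of one probe were averaged. Of the 34127 probes, 33128 were printed once and 999 were printed 10 times. The files name probes by accession, and 25715 probes were matched to a gene symbol, without version numbers, through RefSeq's gene table of assembly GRCh38.p14. The other 8412 probes stayed without a symbol. Because that assembly differs from the one of the array grid, no coordinates are printed and the table served for symbols and gene order alone. The named probes stand for 19683 genes. A gene was represented by the brightest of its probes that were well above background on at least 1 array. For 15 genes, different probes were detected on different arrays, and these genes were not compared.

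The number of arrays limits the precision: with 1 array per group there is no replicate error and no test, and no p-value is given. Genes were counted by a fixed rule of size, a 2-fold difference. A gene well above background on both arrays has a measured difference, SP minus NSP. A gene well above background on 1 array only has a lower bound, written "at least N-fold", taken against the higher of the dim array's own value and the lowest normalized signal among the probes well above background on that array, which was -5.64 on SP and -5.84 on NSP on the log2 scale. Feature Extraction's own error estimates of the 2 signals were combined into an error for each difference, which covers spot error within an array and not the spread between cultures. The 41 gene lists, the rule of size and the alternatives were fixed before the data were examined. For each list with at least 5 members measured on both arrays, the median difference was ranked among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. That percentile describes these 2 libraries. Lists above 97.5% or below 2.5% of the random lists are said to stand apart, and 5% of lists of independently drawn genes would do so. Counts per list are of members 2-fold or more apart and include bounds of at least 2-fold. Symbols in the lists that were not found in the gene table numbered 7 and were left out.

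Genes are named by a rule fixed beforehand: the 12 largest measured differences in each direction, the 4 largest bounds in each direction, up to 4 members with the largest difference or bound in each list, and a fixed set of transporter, stem cell, trophoblast, receptor, cell cycle and FGF response genes. Other genes named were chosen after their values were seen, which holds for FN1, EPCAM, FOXD3, KRT8, KRT18, HSPA1B, CDH2, HLA-A, HLA-E, HLA-F, NFKBIA, IRF9, SPRY1, ABCC3, CD44, MCAM, ID1, ID3, DUSP5, SPRED1, SPRED2, PTPRC, LAPTM5 and TYROBP. The alternatives were normexp background correction (offset 50), quantile normalization and cyclic loess (limma 3.58.1 in R 4.3.3), scaling to the median, stricter and looser filters on dim probes, the mean of a gene's probes, the deposited series table, unmatched random lists and list means. The files hold no mean spot signal, so normexp was run on the median spot signal, a choice made after seeing the data. Calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. The calling of genes was tested on simulated data for the SP against NSP comparison over 13552 genes with a spot noise of 0.15 (log2 SD). It recovered 96% of 50 genes changed by 1.5, and 100% of 50 genes at each of -1.5, 3 and -3, on the log2 scale. It called 0 of 13352 unchanged genes, which noise this far below the 2-fold rule made all but certain. Both simulated arrays took the signals and detection of the NSP array, so the rule for bounds and the spread between cultures were not tested. Of 200 lists of 20 genes drawn at random from the measured genes, 5% stood apart, as the ranking gives by construction.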

Results

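HTR-8/SVneo is an immortalized human trophoblast line derived from first-trimester placenta. Side-population cells are cells that pump out the DNA dye Hoechst through verapamil-sensitive membrane transporters and so appear as a dim tail in flow cytometry, a property used to enrich stem-like cells. The study compared the transcriptome of HTR-8/SVneo SP cells with that of NSP cells after a week in culture, with 1 array per group and no replicates. Of 43118 non-control spots, 26242 (60.9%) were well above background on the SP array and 26928 (62.5%) on the NSP array. The median processed signal was 322 on SP and 330 on NSP, and that of the negative controls was 16.4 and 15.1. Among 19683 named genes, 12202 were measured on both arrays, 980 were well above background on SP only, 1306 on NSP only, and 5180 on neither. The sample labelled NSP carries conflicting labels, and the SP and NSP cells were kept in different media. Each difference below is therefore between 2 cultures that differ in medium, and in sort gate too if the sort label holds.

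The largest measured difference was that of S100P, a calcium-binding protein, which was 3568-fold higher in SP (11.80 ± 0.25 on the log2 scale, spot error, 1 array each). TACSTD2, the epithelial surface protein TROP2, was 1524-fold higher, the keratin gene KRT4 1101-fold higher, and LY6K 1029-fold higher. H2AJ was 552-fold, TRIM29 441-fold, MYADM 435-fold, INPP5D 365-fold, CAV1, which encodes the caveolar protein caveolin 1, 276-fold and RASIP1 258-fold higher in SP. A dimmer MYADM probe was higher by 4.94 on the log2 scale, and a dimmer H2AJ probe, well above background on SP only, gave a bound of at least 1.64-fold. AKR1B15 (366-fold) and AKR1B10 (351-fold) were also higher, but these aldo-keto reductase genes are close paralogs whose probes may not be separable. The non-coding RNA gene UCA1 was well above background on SP only and at least 3958-fold higher there, followed by PSCA (at least 2806-fold), ADIRF (at least 2767-fold) and LY6D (at least 1863-fold).

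In the other direction, COL6A1, a chain of collagen VI, was 343-fold lower in SP (-8.42 ± 0.30 on the log2 scale, spot error). BAG2 was 224-fold lower, LCP1, an actin-bundling protein of blood cells, 219-fold lower, and IGFBP2, a binding protein for insulin-like growth factors, 163-fold lower. TMSB15A was 137-fold, LAMB2 132-fold, TNNC1 128-fold, RAB17 114-fold, MSX1 94.9-fold and HCLS1 90.5-fold lower in SP. PRSS2 (242-fold) and MAGEA6 (154-fold) were lower too, with the same reservation on paralogs, and a further MAGEA6 probe was well above background on NSP only and at least 1469-fold lower. CHGA, which encodes chromogranin A of neuroendocrine granules, was well above background on NSP only and at least 2290-fold lower in SP. It was followed by MAGEA2B (at least 1416-fold), the endoderm transcription factor gene SOX17 (at least 1413-fold) and MGST1 (at least 1379-fold).

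**Figure D1:**
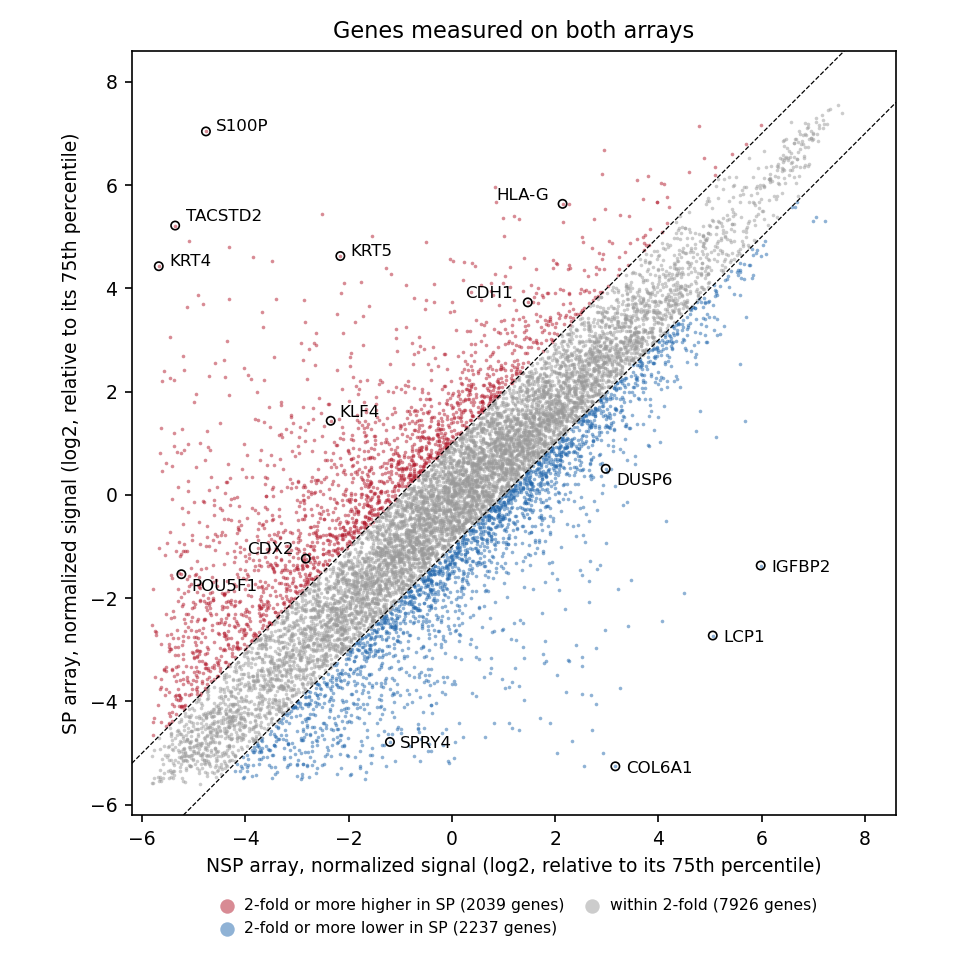
Normalized signal (log2, relative to each array's 75th percentile) on the NSP array (x) and the SP array (y) for genes measured on both arrays, 1 point per gene, with dashed lines at 2-fold. The 2039 genes above the upper line and the 2237 below the lower line lie on both sides of 7926 genes within 2-fold, and S100P is the farthest above.

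In all, 2817 genes were 2-fold or more higher in SP (2039 measured and 778 by their bound) and 3065 were lower (2237 and 828), together 40.6% of the 14503 detected genes. Under cyclic loess the balance turned, with 3177 higher and 2576 lower. At 4-fold, 832 genes were higher and 556 lower by measurement, and 517 more were higher and 559 more lower by their bound. At 32-fold, 91 were higher and 40 lower by measurement. Over genes measured on both arrays the difference had a median of -0.12 and an SD of 1.41 on the log2 scale, and the levels on the arrays correlated across genes with r = 0.848 (Pearson) and 0.845 (Spearman), where genes are not independent replicates. Among 658 probes printed 10 times and measured on both arrays, the SD of the difference between spots of a probe had a median of 0.037, while the SD between probes was 1.48, and 236 of them (35.9%) were 2-fold or more apart. Feature Extraction's error of a difference had a median of 0.20 and ran from 0.06 to 0.35 for the named genes. Of 872 genes past 2-fold with several measured probes, 776 (89.0%) had all probes on one side of zero and 22 had probes 2-fold or more apart in opposite directions. These errors are those of spots and probes, and the spread between cultures of one group was not measured.

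The transporters that pump Hoechst out of side-population cells bear on the sort. The cells had spent a week in different media, so transporter RNA need not mirror the sort gate. ABCG2, the main Hoechst exporter of most side populations, was well above background on SP only and at least 10.9-fold higher there. ABCB1, the verapamil-sensitive P-glycoprotein, went the other way: it was well above background on NSP only, by both of its probes, and at least 15.6-fold lower in SP. ABCC1 differed by 0.18 ± 0.20, less than its spot error. Of the 13 detected members of the list of ABC transporters, 8 were higher in SP and 2 lower, with ABCC2 194-fold, ABCC3 3.04-fold and ABCG1 at least 42.7-fold higher. The list's median difference was 1.60 over the 9 members measured on both arrays, which include neither ABCG2 nor ABCB1. It lay at percentile 99.8 of matched random lists, whose central 95% ran from -0.95 to 0.85.

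Members of the pluripotency list went both ways. POU5F1, which encodes the pluripotency factor OCT4, was 13.0-fold higher (3.70 ± 0.30), KLF4 13.8-fold and SALL4 24.7-fold higher. SOX2 was at least 52.8-fold and NANOG at least 3.83-fold higher, both well above background on SP only. FOXD3 was 3.69-fold lower. Of the 11 detected members of the pluripotency list, 5 were higher, 2 lower and 7 more were not detected on either array. Its median over the 8 members measured on both arrays, 0.22, lay at percentile 77.0 (0.40 with bounds), so as a group it did not stand apart, although with no filter on dim probes it did (percentile 98.2). The unfiltered value also counts the 7 undetected members, whose signals were not well above background on either array. POU5F1 has transcribed pseudogenes, so its probes are not certain to be specific.

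Of the 3 trophoblast lists, that of stem and cytotrophoblast genes had most members higher in SP. In it 14 of 22 detected members were higher and 4 lower, and the median of 1.48 lay above all matched random lists (percentile 100). The list shares CDH1, KRT7, KRT8 and KRT18, among others, with the epithelial list, which was also higher. The ranks of these lists are therefore not independent. GATA3, a regulator of trophoblast fate, was at least 19.7-fold higher and TP63, the marker of proliferating cytotrophoblast, at least 9.98-fold higher, both on SP only. EGFR was 9.81-fold higher, ITGA6 9.30-fold, CDX2 3.02-fold, TFAP2C 2.79-fold and EOMES 2.11-fold, the last within 2-fold (0.85) after normexp. A dimmer EGFR probe was higher by 1.15 on the log2 scale. KRT7, a pan-trophoblast keratin, differed by 1.48-fold, less than the rule of size. PEG10, an imprinted placental gene, was on NSP only and at least 173-fold lower in SP. ELF5, a trophoblast stem cell factor, was on NSP only and at least 2.20-fold lower, though within 2-fold (-0.63) after normexp.

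Markers of invasive extravillous trophoblast gave 6 of 14 detected members higher and 5 lower, with a median of 1.12 over the 9 measured on both arrays and 0.65 with bounds (percentile 99.6, and percentile 94.2 with no filter on dim probes). PLAC8 was 225-fold, ASCL2 12.3-fold and HLA-G, the non-classical class I molecule of invasive trophoblast, 11.3-fold higher in SP. HLA-G was read by 1 probe, which may bind related class I genes that were also higher. ITGA5 was 5.41-fold lower and FLT4 at least 6.05-fold lower. PLAC8 has a further probe that was not well above background on either array. In the list of syncytiotrophoblast genes, 9 of 22 members were detected, 3 of them higher and 2 lower, and the median of 0.48 lay at percentile 83.0. SLC40A1 was at least 11.4-fold and PGF 3.30-fold lower, OVOL1 2.79-fold and TFPI2 at least 2.76-fold higher.

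**Figure D2:**
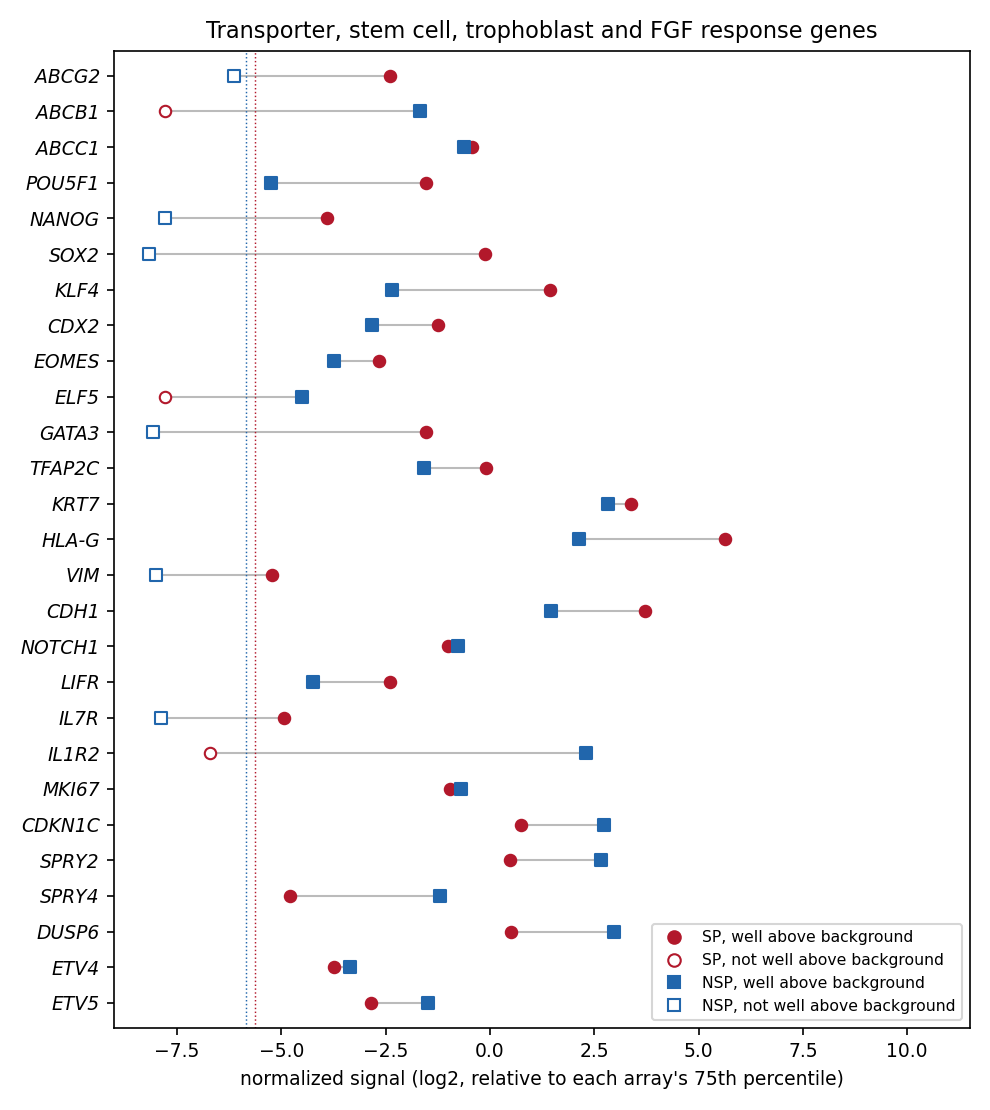
Normalized signal (log2, relative to each array's 75th percentile) of genes fixed beforehand on the SP array (circles) and the NSP array (squares), with open symbols where the gene was not well above background and dotted lines at the lowest signal that was, -5.64 on SP and -5.84 on NSP. ABCG2, SOX2, NANOG and GATA3 have filled symbols on SP alone, and ABCB1, ELF5 and IL1R2 on NSP alone.

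Surface receptors used to describe side populations split. IL1R2, a decoy receptor for interleukin 1, was on NSP only and at least 247-fold lower in SP, IL1R1 at least 37.1-fold and CXCR4 at least 28.4-fold lower, and MCAM was 16.6-fold lower. NT5E, which encodes CD73, was at least 65.1-fold higher, CD44 4.68-fold and LIFR, the receptor for leukaemia inhibitory factor, 3.58-fold higher. IL7R was well above background on SP only and at least 1.87-fold higher, short of the rule of size. In all 5 of 15 detected members were higher and 8 lower. The median over the 8 members measured on both arrays was 0.97 (percentile 97.0, and percentile 98.8 against unmatched random lists), and with bounded members at their bounds it was -1.01.

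Genes that respond to FGF and MAPK signalling also split, 7 of 22 higher and 8 lower, with a median of 0.07 (percentile 80.8, and -0.16 with bounds). Feedback inhibitors of FGF and MAPK signalling went both ways on the SP array, whose medium held FGF2. SPRY4 differed by -3.58 on the log2 scale, DUSP6 was 5.55-fold lower, SPRY2 4.52-fold and SPRY1 3.98-fold lower. The FGF-induced factor ETV5 was 2.60-fold lower, while ETV4 differed by 1.32-fold. A further SPRY4 probe close to background differed by -0.32. FOSL1, a component of AP-1, was 18.6-fold higher and the phosphatase genes DUSP4 and DUSP5 were 10.8-fold and 5.03-fold higher, while SPRED1 and SPRED2 differed by less than 2-fold.

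Epithelial and mesenchymal genes were compared as lists. All 24 epithelial members were measured on both arrays, 13 were higher and 4 lower, and the median of 1.31 lay at percentile 100. KRT14 was 141-fold, KRT17 130-fold and KRT5 110-fold higher, all keratins of basal epithelium, and CDH1, which encodes E-cadherin, was 4.79-fold higher. EPCAM was 2.62-fold and KRT8 3.08-fold lower. Of 13 detected mesenchymal genes 3 were higher and 7 lower, with a median of -1.06 (percentile 1.43, and 20.95 when list means were used). SNAI1 was 6.42-fold lower, while SNAI2, the related repressor SLUG, was at least 82.8-fold higher, ACTA2 21.5-fold and COL5A2 9.85-fold higher. VIM, which encodes the mesenchymal filament vimentin, was barely above background on SP (log2 level -5.21) and not on NSP. FN1 was not well above background on either array, by a single named probe that may not read all transcripts of the gene.

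Genes of the extracellular matrix differed strongly in both directions, with 7 of 19 detected members higher and 7 lower. Besides COL6A1, COL6A2 was at least 28.8-fold and TNC 27.5-fold lower, and LAMA3, a chain of epithelial laminin, was 19.3-fold higher. The median of 0.75 lay at percentile 99.3, but it was -0.02 with bounds, and the list did not stand apart with list means (percentile 71.0) or with no filter on dim probes (72.0). Matrix proteases and their inhibitors had 13 of 18 detected members higher and 2 lower (median 2.12, and 1.58 with bounds, percentile 100). MMP14 was at least 48.6-fold, PLAU, the urokinase, 38.9-fold, TIMP4 13.6-fold and PLAUR, the receptor of urokinase, 8.38-fold higher. Of 14 detected integrins 4 were higher and 4 lower (median 0.24, and 0.0015 with bounds, percentile 84.6), among them ITGA6, ITGB4 (9.06-fold) and ITGA3 (7.24-fold), higher, and ITGA5, lower.

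Interferon-stimulated genes were higher in SP. Of 23 detected members 17 were higher and 0 lower, and the median of 1.92 (2.98 with bounds) lay above nearly all matched random lists (percentile 100). TAP1, the peptide transporter of antigen presentation, was at least 492-fold higher, MX1 at least 172-fold, PSMB8, a subunit of the immunoproteasome, at least 142-fold, IFI44L 70.9-fold and IRF9 32.2-fold. In the MHC list the class I genes and B2M were higher: HLA-C was 20.6-fold, HLA-B 11.2-fold, HLA-E 8.41-fold, HLA-F 5.58-fold, B2M 4.18-fold and HLA-A 3.97-fold higher, with reservations because class I probes can bind related genes. The class II pathway gene HLA-DMB was at least 29.7-fold lower. In total 7 of 14 detected members were higher, 4 lower and 3 within 2-fold, with a median of 2.06 over the 11 measured on both arrays and 1.26 with bounds (percentile 100, and 94 with no filter on dim probes).

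Feedback targets of NF-kappaB gave 11 of 14 higher and 2 lower (median 1.88, percentile 100). BIRC3 was 21.2-fold, NFKBIZ 9.80-fold, ICAM1 6.77-fold, BCL3 4.63-fold and NFKBIA 3.74-fold higher. Only 4 cytokines and chemokines were measured on both arrays, too few to rank (median -0.05, mean 0.21, and median 1.34 with bounds), but 7 of 14 detected members were higher and 1 lower, led by IL1B (at least 182-fold), IL1A (at least 45.2-fold), LIF (at least 26.1-fold) and CCL20 (at least 15.4-fold), each on SP only. A further LIF probe was not well above background on either array. Among markers of macrophages and leukocytes, 13 of 19 were not detected or had no named probe, 2 were higher and 0 lower, and the median of 0.16 (0.52 with bounds) lay at percentile 65.2. CD14 was 4.59-fold and CD68 4.58-fold higher, S100A9 was at least 1.84-fold higher and FCER1G differed by 1.51-fold.

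Signalling lists that stood above random lists included TGF-beta and BMP (13 of 21 higher, 3 lower, median 1.22, percentile 100) and Wnt (9 of 19 higher, 4 lower, median 1.11 over 13 genes and 0.55 with bounds, percentile 99.5). INHBB was 119-fold, BMP2 at least 47.0-fold, SMAD6 20.4-fold and TGFBI 18.2-fold higher. The BMP target genes ID3 and ID1 were 6.41-fold and 3.89-fold higher. DKK1, a secreted Wnt inhibitor, was 119-fold and WNT10A at least 29.2-fold higher, while NKD2 was at least 60.8-fold and SFRP1 at least 13.7-fold lower. The Wnt list was inside the random range with the mean of a gene's probes (percentile 95.6) and with no filter on dim probes (percentile 90.7). The Notch list did not stand apart, with 6 of 19 higher and 2 lower (median -0.07, mean 0.21, percentile 54.9). In it DLL1 was 8.37-fold and LFNG 4.03-fold higher and HEYL 5.76-fold and NOTCH3 4.06-fold lower. NOTCH1 was 1.17-fold lower on its brightest probe and higher by 2.32 on the log2 scale on its dimmer probe, so it has no clear direction. A dimmer LFNG probe was higher by 0.48.

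The growth factor gene IGF2 and the binding protein gene IGFBP2 were lower in SP, IGF2 17.7-fold by the 1 of its 2 probes that was detected. IRS2 was 14.6-fold and IRS1 10.8-fold higher. The IGF list had 5 of 15 detected members higher and 5 lower, and its median of 0.85 (percentile 98.6, and 0.24 with bounds) was inside the random range with no filter on dim probes (66.3) and with list means (69.4). Imprinted placental genes were lower, 10 of 16 against 1 higher, with a median of -1.07 (percentile 0.505, and -1.28 with bounds). PEG10 was followed by SGCE, its neighbour, at least 108-fold, and CDKN1C, an imprinted cell cycle inhibitor, was 3.97-fold lower. The exception was H19, on SP only and at least 163-fold higher.

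Genes of the cell cycle were compared in 3 lists. Of 25 measured G2/M genes 0 were higher and 7 lower, and the median of -0.64 lay at percentile 1.43, but inside the random range after normexp (2.73) and with list means (3.54). BIRC5 was 3.31-fold, BUB1B 2.47-fold, CCNB1 2.24-fold and KIF20A 2.24-fold lower, where CCNB1 fell short of 2-fold under cyclic loess (-0.92) and with the mean of its probes (-0.81), and KIF20A fell just short under cyclic loess. MKI67, a marker of cycling cells, was 1.19-fold lower on its brightest probe but higher by 0.70 and 0.98 on the log2 scale on its others, so it has no clear direction. G1/S genes were 0 higher and 6 lower of 26 (median -0.38, percentile 21.7, and 1.46 with list means), with RRM2 lower by a log2 difference of -2.89, and CCNE1 5.75-fold, CDK2 4.04-fold and E2F1 2.83-fold lower. Arrest genes and p53 targets were 6 higher and 7 lower of 22 (median -0.01, and 0.17 with bounds, percentile 70.3), led by SPATA18, at least 89.2-fold higher, TP53I3, 7.75-fold lower, BTG2, higher by 2.89 on the log2 scale, and ZMAT3, 4.35-fold higher.

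Among stress and metabolic lists, oxidative stress and detoxification stood above random lists (9 of 24 higher, 4 lower, median 0.61, percentile 99.9). GPX2 was at least 612-fold and ALDH3A1 31.0-fold higher, and GPX3 51.2-fold lower. Heat shock genes stood below (2 of 15 higher, 8 lower, median -0.79, and -1.13 with bounds, percentile 1.16, and 32.1 with list means). CRYAB was 12.4-fold, HSPA8 3.06-fold and HSPA6 at least 2.96-fold lower, the last within 2-fold (-0.80) after normexp. HSPA1A was 46.6-fold higher and its near-identical copy HSPA1B differed by 1.22-fold, so the probes of this pair are uncertain. Cholesterol synthesis genes stood below (4 of 22 higher, 8 lower, median -0.78, percentile 0.24, and 5.87 with list means), with DHCR24 4.99-fold and CYP51A1 3.17-fold lower. PCSK9 was 9.93-fold and EBP 4.31-fold higher. Lists inside the random range were unfolded protein and amino acid stress (5 of 25 higher, 3 lower, median 0.02), hypoxia and glycolysis (6 of 22 higher, 5 lower, median -0.35), fatty acid and lipid storage (2 of 15 higher, 5 lower, median -0.31) and mitochondrial respiration (0 of 23 higher, 4 lower, median -0.50, and at percentile 2.47 with no filter on dim probes). In these, DDIT3 was 4.62-fold lower and HSPA5 3.37-fold higher, ANGPTL4 was at least 8.52-fold and NDRG1 6.72-fold higher, FADS2 was 11.1-fold lower and PPARG 4.90-fold higher, and PPARGC1A was at least 100.0-fold lower.

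Ribosomal protein genes, which serve as a reference of stable expression, were all within 2-fold (28 genes), with an interquartile range of -0.07 to 0.08. The largest difference among them was that of RPL5, 1.22-fold on its brightest probe and -0.95 on the log2 scale on its dimmest. The median was 0.01 and, under cyclic loess, 0.32. Of 18 housekeeping references, 1 was higher and 3 lower (median -0.18, and 0.10 under cyclic loess), namely B2M, and TUBA1B (3.21-fold), TFRC (3.09-fold) and PGK1 (2.81-fold). Replication-dependent histone genes were 3 higher and 3 lower of 18 (median 0.02, mean -0.04, and median 0.10 with bounds), led by H1-5, at least 48.2-fold higher.

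The ranked lists of other lineages and regulators stayed inside the random range. HOX genes were 7 higher and 11 lower of 29 (median -0.34, percentile 14.6), with HOXA3 at least 50.5-fold and HOXC13 45.3-fold higher and HOXD13 at least 36.1-fold and HOXB6 25.1-fold lower. Of 10 detected germ layer genes 4 were higher and 4 lower (median 1.07, and -0.43 with bounds, percentile 97.2), among them GATA6, 19.6-fold higher, and MESP1, 13.1-fold lower. The list passed just above the random range when only probes above background on both arrays were used. Epigenetic regulators were 3 higher and 4 lower of 18 (median -0.38), with TET1 at least 37.9-fold and DNMT3A 28.8-fold lower. Endothelial and angiogenic genes were 4 higher and 4 lower of 13 (median 0.25, and -0.03 with bounds), with VWF at least 7.94-fold lower and VEGFC 7.05-fold higher. Fibroblast and stroma genes were 3 higher and 4 lower of 9 (median -0.14, mean 0.92, and median -0.32 with bounds), with THY1 at least 13.0-fold lower and PDPN 10.2-fold higher. Only 3 neural genes were measured on both arrays (median 0.31, and 0.02 with bounds, not ranked), and 3 of 8 detected were higher, led by NEFL, at least 233-fold, and 3 lower, led by PAX6, at least 22.9-fold.

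**Figure D3:**
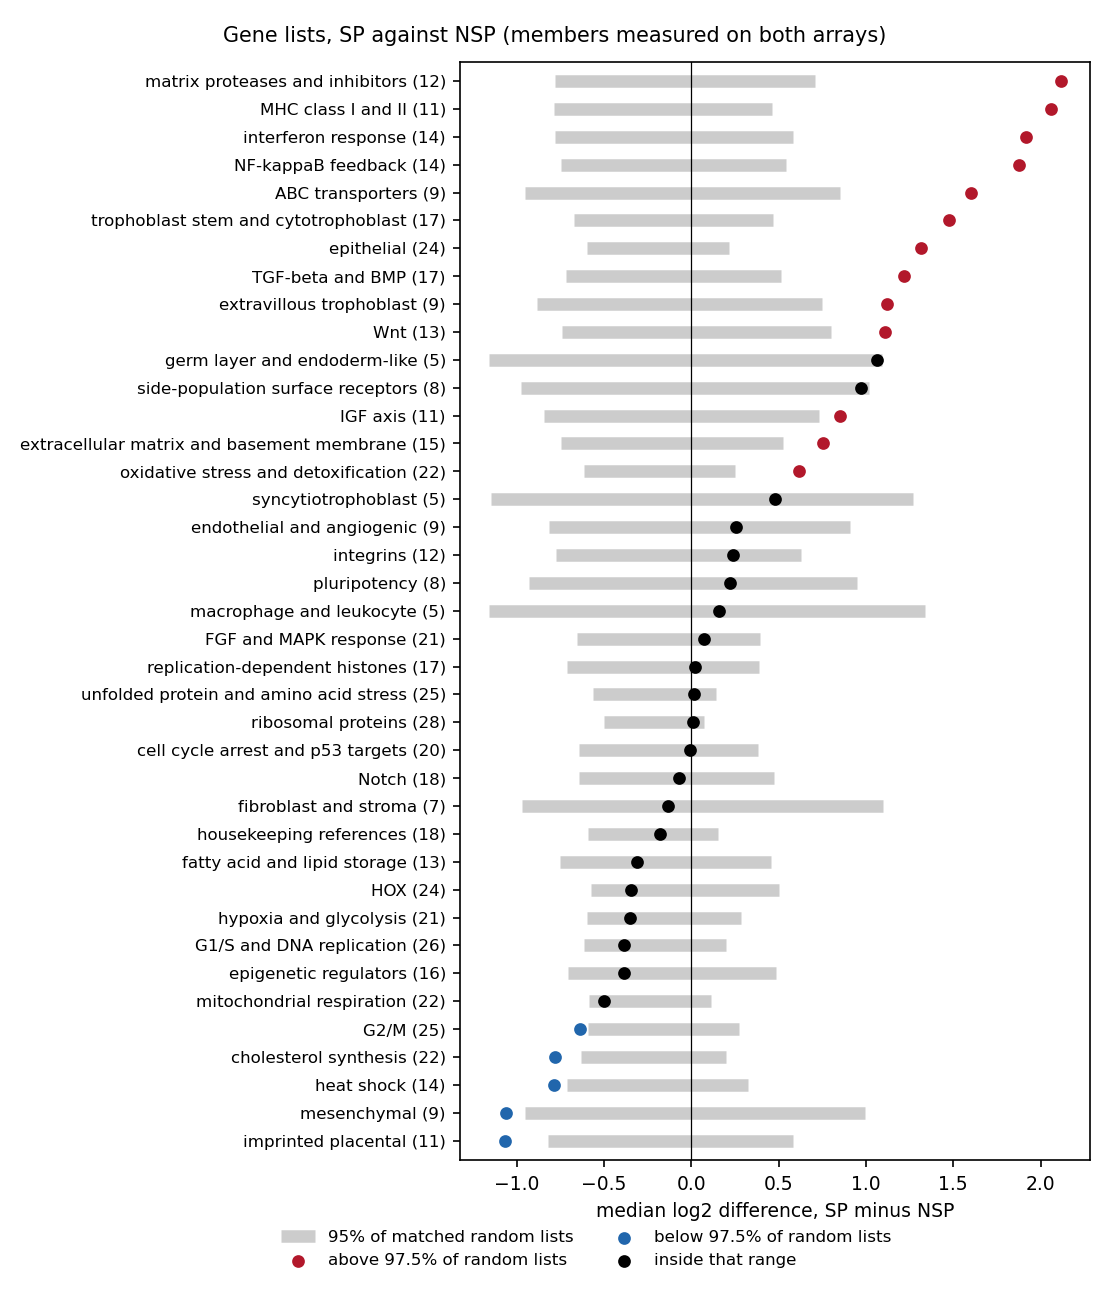
Median log2 difference (SP minus NSP, x) of 39 gene lists (y, with the number of members measured on both arrays), with grey bars for the central 95% of 10000 matched random lists. Above the bars lie 13 lists, led by matrix proteases and inhibitors at 2.12, and below them 5, the lowest being imprinted placental genes at -1.07.

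Altogether 39 lists were ranked, of which 13 stood above and 5 below matched random lists. For lists of genes drawn independently, 1.95 would lie outside. Members of a real list can move together, which the random lists do not model, so the 2 counts cannot be set against that value as an excess over chance. Every list was a description of these 2 arrays, and lists that share members were not independent. The medians of the ribosomal, histone, arrest and p53, Notch, unfolded protein and housekeeping lists lay close to zero and changed sign under at least 1 of the other scalings or background corrections, so no direction is given for them.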

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

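The tests for gene order, for exchanged labels and for leukocyte RNA were chosen only after the results they bear on had been seen, and those for spot noise and for a signal-dependent bias before.

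The probes without a gene symbol were not used in any comparison, yet 700 of the 2445 that were well above background on both arrays were 2-fold or more apart, 393 higher in SP and 307 lower. This is 28.6% of them, against 35.0% of named genes. There is no control sample to set this against.

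The breadth of the difference, with 40.6% of detected genes 2-fold or more apart between 2 cultures labelled as one line, invites a technical reading first. Spot noise is argued against, since the SD between probes printed 10 times was 39.7 times the SD between spots of a probe, which says nothing of the spread between cultures. A signal-dependent bias as the source of the breadth is argued against too, since 97.8% as many genes were 2-fold apart after cyclic loess. All 2817 higher genes kept their call under it but only 2568 of the 3065 lower ones, so single calls near 2-fold can depend on such a bias. A candidate explanation that remained open is that the cultures differed in gene copy number over large regions or held different clones or lines: differences of autosomal genes 40 places apart in gene order correlated with r = 0.0524 across 11797 genes, above the highest of 1000 shuffles (0.0310), although an r of this size leaves most of the breadth unaccounted for and shared regulation of neighbouring genes would also give it. The sorted population and the medium, of which the conflicting labels leave open whether both or only the medium differed, stay open and untested as biological explanations.

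Some FGF feedback and response genes (SPRY2, SPRY4, DUSP6 and ETV5) were lower on the SP array although its medium held FGF2, while DUSP4 and DUSP5 were higher and SPRED1 and SPRED2 were within 2-fold. If the labels of the 2 arrays had been exchanged, the transporters that define the SP gate would be lower on the SP array. That holds only if their RNA still followed the gate after a week in different media, which was not tested. The transporter list was higher (median 1.60), but that median rests on 9 members that include neither ABCG2 nor ABCB1. ABCG2 was higher and ABCB1 lower on the SP array, so the transporters do not settle it. Exchanged labels cannot be told apart from a difference between the sorted cells or their media. The description of the NSP sample as SP cells in basal medium keeps this open too, and under that reading the comparison would be between media.

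Interferon and MHC class I genes were higher in SP, as they would be if leukocyte RNA had been present. Of the 4 leukocyte genes tested that have a named probe, 1 (CD14) was both well above background and 2-fold higher on the SP array, and CD68, of the wider list fixed beforehand, was 4.58-fold higher. PTPRC, by all 4 of its probes, and LAPTM5 were not well above background there, and TYROBP differed by 0.16 on the log2 scale. Other genes went the other way: LCP1, of blood cells, was 219-fold lower in SP and the class II pathway gene HLA-DMB at least 29.7-fold lower. LCP1 was bright on NSP (log2 level 5.05), where PTPRC was not well above background either, so LCP1 need not mark leukocytes here. The 4 leukocyte genes were picked, and the limit set, after the values were seen. Those not found lie at the floor, and the other genes named here went both ways, so leukocyte RNA stays open. The medium conditioned by mouse cells and the sorted population also stay open, as biological explanations, untested.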

How the results depend on the processing

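Normexp on the median signals was chosen after the data had been seen, and the other alternatives before. Under the 8 alternatives that bear on single genes, 2044 to 3351 genes were higher and 2239 to 3777 lower in SP, each within 1.5 times the main count, and 0 genes 2-fold apart changed sign. Cyclic loess moved the median difference by 0.16 and the share of higher genes from 47.9% to 55.2%, and using all probes with no filter moved the median by 0.24. Of the 18 lists that stood apart, 9 did so under each of the 10 alternatives: 8 above (ABC transporters, trophoblast stem and cytotrophoblast, TGF-beta and BMP, epithelial, matrix proteases, NF-kappaB, interferon, oxidative stress) and 1 below (imprinted placental). Median scaling and the deposited series table shifted nearly all differences by the same amount, so they could hardly move a percentile. With list means in place of medians 2 lists stood below random lists, against 5: mesenchymal, G2/M, heat shock and cholesterol genes came inside the random range and G1/S genes went below it, and the cause was not tested. Of 189 named genes 2-fold apart, 6 fell within 2-fold under an alternative, and none reversed. Single lists gave 329 values within a limit around the main median and 61 beyond it. The limit was the interquartile range divided by 2 and by the square root of the number of measured members. It is narrower than the spread of the members. Named genes gave 1329 values within their spot error and 226 beyond it, 92 of these under normexp, whose offset compresses low signals. Signal over background limits the rest: 980 genes were well above background on SP only and 1306 on NSP only, and have bounds, and 5180 have no comparison. No paired analysis was possible because each group has 1 array.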

Other observations

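The correlation by gene order was tested only after the results had been seen, and the levels below were also chosen then. By each gene's brightest probe, KRT18 lay at percentile 98.1 of detected genes on SP and 98.7 on NSP, EPCAM at 94.0 and 97.8, KRT7 at 92.5 and 88.2, and KRT8 at 78.2 and 91.2. VIM lay at percentile 1.32 on SP and was not well above background on NSP, by a single probe. FN1, also by a single named probe, was not well above background on either. CDH2, which encodes N-cadherin, was measured on both and 1.69-fold lower in SP. The brightness of a probe also depends on its sequence, and no explanation was tested. Whether the arrays hold the cells that the labels name was not tested either.

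Differences of neighbouring autosomal genes correlated with r = 0.124 across 11797 genes, above the highest of 1000 shuffles (0.0294), and the correlation at 40 places apart was 0.0524. Adjacent genes that went together include PEG10 and SGCE, both on NSP only and at least 173-fold and 108-fold lower in SP, and COL6A1 and COL6A2. A candidate explanation is regional regulation or copy number, which these expression data do not separate.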
